A study of Mus musculus with 6 samples.

How the data were processed

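The series holds 6 RNA sequencing libraries of mouse lens capsules with their lens epithelial cells, 3 taken at the time of cataract surgery (0 h) and 3 taken 5 days later. Per the labels' protocols, the mice were C57BL/6 wildtype, each library came from 5 pooled capsules, and libraries were made from total RNA with the SMARTer Stranded Total RNA-Seq Pico kit. Per the series description, 1 eye was operated on first, and 5 days later the second eye was operated on and the capsules of both eyes were taken. The labels do not say whether replicate numbers pair pools, or whether a 0 h and a 5 day pool share mice. The deposited values are raw counts per Ensembl gene, made with HISAT2 and HTSeq on build GRCm39, per the submitters' processing notes, which also name edgeR. Tool versions, annotation release, strand setting and counting mode are not given in the sources used here, so counts of overlapping or antisense genes and of near-identical copies are uncertain.

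Each library listed 56940 genes, of which 91.23% took a symbol from GENCODE M21 (build GRCm38) by Ensembl identifier. That release is older than the build of the counts and served for symbols and gene types alone, and no coordinates were used. Genes without a symbol held 0.83 to 1.37% of the counts, stayed in all tests, and are not named. The 5 HTSeq summary entries per library, 32.26 to 42.55% of all reads, were left out, among them reads in no gene (12.56 to 23.05%). The remaining gene counts were 7709815, 9774343 and 8707928 at 0 h and 6207387, 7509954 and 8682659 at 5 days. With 3 libraries per time, exact permutation tests of single values cannot go below p = 0.1. Correlations of log values were 0.965 to 0.979 within a time and 0.785 to 0.83 between times.

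Genes were kept by the default low-count filter of edgeR (14676 genes), scaled with TMM, and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common biological coefficient of variation was 0.156. Counts of 2-fold changes are genes that passed this test and had a log2 fold change of at least 1 in size. Standard errors are those of the log2 fold change. For 33 gene lists fixed before any count was seen, members called higher and lower were counted, also adjusted over the list alone, and 31 lists with at least 3 tested members were tested against the other genes with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation, and with fry. The directional p of fry tests movement one way and its mixed p movement either way, and neither compares a list with other genes. A gene with no counts in a group is given as a bound against 3 counts over that group, and one with 1 to 3 counts as a ratio with a 95% exact counting interval. Shares of counts were compared by exact two-sided permutation.

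Named genes follow a rule fixed before any count was seen. It takes the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 5, groups that do not overlap and an official symbol, with at most 3 crystallins. From each list it takes the called member of highest expression, the called member of largest change in the main direction and the largest in the other, and it adds 13 standard markers. Some genes that the rule names are not reported here. Other list members given as examples were chosen after their values were seen. The added lists of the closing section (other retinal cells, muscle membrane, wound keratinocytes, fibrinolysis) were also composed after values were seen. The retinal list takes all 35 names whose values had been displayed, and none of these lists was tested for enrichment.

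The other settings tried, chosen before any count was seen, were DESeq2 size factors, total library size, scaling without crystallin, mitochondrial and ribosomal RNA genes, no low-count filter, a filter of at least 2 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, replicate blocks by title or library name number, and each library left out in turn. A count without markers of other cell types was added after seeing the data. In counts simulated for 5 days against 0 h (14325 genes), edgeR's quasi-likelihood test recovered 68% of 2-fold and 89.9% of 4-fold changes, and 9.4% of its calls were false (16 of 14129 unchanged genes). In the same simulation camera called 0 of 100 unchanged lists and 20 of 20 lists raised 1.5-fold. The simulated genes were drawn independently of each other, whereas the photoreceptor list, for one, had an estimated correlation of 0.723 in the data. Most simulated genes were unchanged, whereas 47.6% of the tested genes were called in the data. The simulated rates of false calls, for genes and for lists, therefore do not carry over to these data. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.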

Results

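RNA was sequenced from mouse lens capsules and the lens epithelial cells attached to them, in a mouse model of cataract surgery. In this operation the fiber cell mass is taken out through an opening at the front of the lens, while the capsule and its epithelium stay in the eye. Capsules collected at the time of the operation (0 h) were compared with capsules collected 5 days later. Each library was made from a pool of 5 capsules, with 3 libraries at each time, all from wildtype C57BL/6 mice. The 0 h capsules came from the second eye of mice whose other eye had been operated on 5 days earlier, so the 0 h animals were not free of surgery. The libraries held 7709815, 9774343 and 8707928 gene counts at 0 h and 6207387, 7509954 and 8682659 at 5 days. Values below are normalised counts (CPM) as mean ± SD with n = 3, or log2 fold changes of 5 days over 0 h with their standard error (SE).

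The comparison asked which transcripts of the lens epithelium differ 5 days after cataract surgery. Most tested genes of the lens fiber program fell, and most of the tested interstitial matrix, contractile and inflammatory genes rose, while basement membrane genes went both ways. Fibronectin (Fn1, ENSMUSG00000026193), a matrix glycoprotein of healing wounds, rose from 22.6 ± 5.71 to 7344 ± 2944 CPM (n = 3), a log2 fold change of 8.35 (SE 0.35). The lens chaperone αA-crystallin (Cryaa, ENSMUSG00000024041) fell from 62310 ± 7081 to 11190 ± 5575 CPM (n = 3), a log2 fold change of -2.48 (SE 0.34). The leukocyte antigen CD45 (Ptprc, ENSMUSG00000026395) rose from 1.23 ± 0.504 to 41.5 ± 3.81 CPM (n = 3), a log2 fold change of 5.04 (SE 0.23). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 6.52e-09 for Fn1, 7.65e-05 for Cryaa and 1.28e-08 for Ptprc, and for each of these genes the 3 libraries of 5 days did not overlap the 3 of 0 h.

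**Figure D1:**
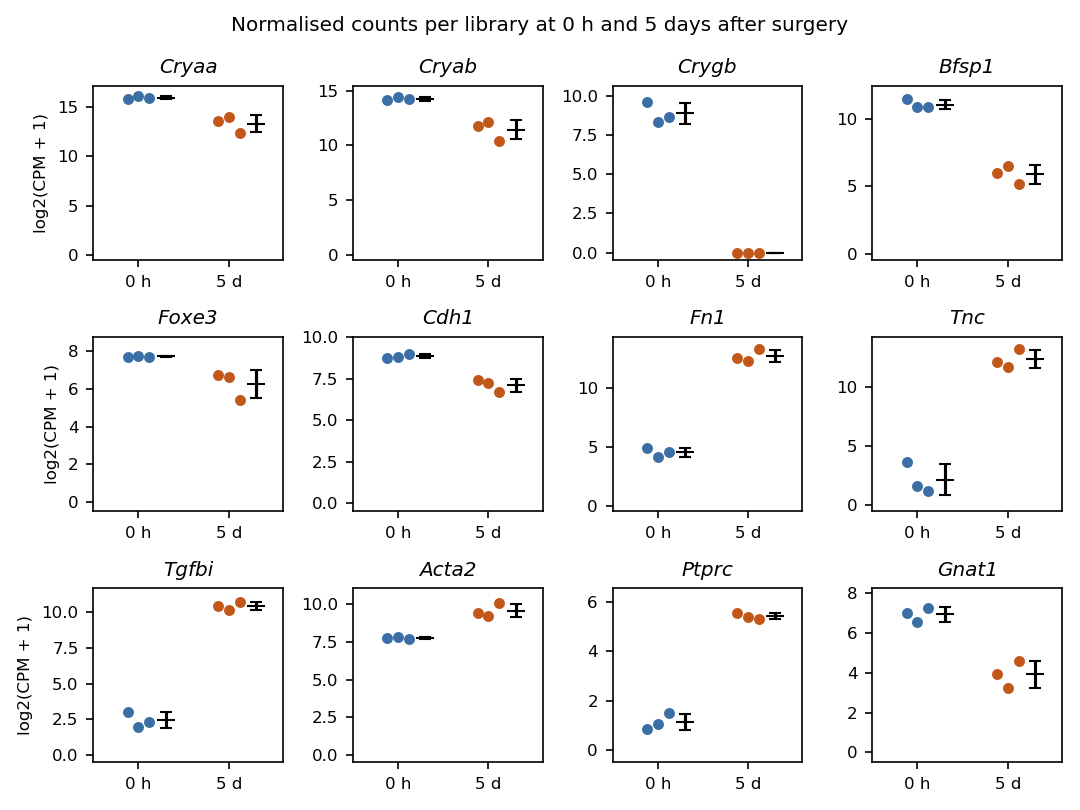
Normalised counts of 12 genes in the 3 libraries at 0 h (blue) and the 3 at 5 days (orange), as log2 of CPM plus 1, with the mean and SD of the 3 log2 values in black. Crygb had no counts at 5 days, Fn1 lay at 28.42 CPM or below at 0 h and at 5267 CPM or above at 5 days, and no gene's 0 h and 5 day points overlap.

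Of 14676 genes tested, 6984 (47.6%) changed at an adjusted p under 0.05, 3683 upward and 3301 downward. Changes of at least 2-fold were called for 2125 genes upward and 1597 downward, and changes of at least 16-fold for 536 upward and 69 downward. The CPM values of the 3 libraries at 5 days did not overlap those at 0 h for 58.1% of the tested genes, where chance gives 10%. The first principal component separated the times and held 83.7% of the variance, and the second (5.1%) set replicate 3 at 5 days apart from the other libraries. With total library size in place of TMM scaling, log2 fold changes shifted upward by a median of 0.13, and 62.9% of the calls were upward against 52.7% with TMM.

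The crystallins, the abundant refractive proteins of the lens, all fell. Of 16 listed genes 15 were tested and 15 were lower, with a median log2 fold change of -4.27, and the 15 calls held under each of the 4 scalings. Cryab fell from 19620 ± 2143 to 3107 ± 1575 CPM (n = 3), and the β-crystallins Crybb2 and Cryba4 fell by 3.15 and 5.65 on the log2 scale. The γ-crystallins Crygb to Crygf, which are typical of fiber cells, fell furthest, while Crygs and Crygn fell by 3.01 and 5.24. Crygb went from 503.1 ± 249 CPM (n = 3) to no counts, at least 3795-fold lower against a floor of 3 counts over the group (such floors and intervals cover counting error alone), and Crygd was 5977-fold lower (95% counting interval 1654 to 49360). γ-crystallin genes are close copies of each other, so the split of reads among them is uncertain. As a share of all gene counts, crystallins made up 15.64 ± 1.15% at 0 h and 2.39 ± 1.34% at 5 days (n = 3), with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give.

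Other fiber cell genes followed. Of 25 tested, 23 fell and 1 rose, with a median log2 fold change of -2.30. The beaded filament protein Bfsp1 fell from 2172 ± 522 to 62.4 ± 28.7 CPM (n = 3), and the water channel Mip fell by 3.55 on the log2 scale. Birc7 was at least 94.1-fold lower, with no counts at 5 days. The glucose transporter Slc2a3 was the member that rose, by 3.12 (SE 0.30). Replicate 3 at 5 days was the lowest of its group for 11 of the 15 crystallins and 17 of the 23 lower fiber genes, where chance gives 33.3%. Camera called the crystallins lower (adjusted p = 3.71e-16) and the other fiber genes lower (adjusted p = 1.1e-12). Both calls were lost when the correlation was estimated, with adjusted p = 0.169 with an estimated correlation for each. The FGF and ERK genes, with an estimated correlation of -0.036 against 0.374 for the crystallins, also had adjusted p = 0.169 in that camera test. Calls were thus also lost without correlation within a list, and how far correlation accounts for the loss in the crystallins and other fiber genes was not tested.

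Genes of the lens epithelium fell less, and not uniformly. Of 25 tested, 17 fell and 2 rose, with a median log2 fold change of -0.74 and 3 higher and 17 lower when adjusted over the list alone. The transcription factor Foxe3, needed for the lens epithelium, fell from 211.4 ± 4.38 to 82.4 ± 35.5 CPM (n = 3). E-cadherin (Cdh1), the epithelial adhesion protein, fell from 462.9 ± 45.1 to 139.3 ± 35.2 CPM (n = 3). The largest fall in the list was in Npnt, an integrin ligand of the basement membrane, at -4.66 (SE 0.14). Pitx3 and Aldh1a1 fell by 1.68 and 1.66, while Sox2 and Six3 were not called, at -0.15 and 0.01. The count of 2 that rose was 1 or 0 without any single library, 1 with a stricter filter, and 3 under each of the other scalings. Pax6, the eye field regulator, passed with a small rise of 0.28 (SE 0.11), from 651.5 ± 36.6 to 790.8 ± 55.4 CPM (n = 3), at an adjusted p of 0.0483 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. That call was lost when any library other than replicate 3 at 5 days was left out, where the Pax6 log2 fold change was 0.24 to 0.32, and also without or with a stricter low-count filter. Epha2 rose by 0.43 (SE 0.15), and its call was lost without replicate 2 or 3 at 0 h or replicate 1 or 3 at 5 days, where the Epha2 log2 fold change was 0.30 to 0.40. Camera called the list lower (adjusted p = 1.77e-06), with adjusted p = 0.169 with an estimated correlation.

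Matrix genes of wounds and scars rose. Of 40 interstitial and provisional matrix genes tested, 29 rose and 3 fell, with a median log2 fold change of 3.73 and 29 higher and 4 lower when adjusted over the list alone. Tenascin C (Tnc) rose from 4.99 ± 5.62 to 5730 ± 3279 CPM (n = 3), a log2 fold change of 10.22 (SE 0.71). Fbln2 rose by 9.56 (SE 0.52), osteopontin (Spp1) by 8.85 (SE 0.64) and the TGF-beta-induced protein Tgfbi by 8.20 (SE 0.28) on the log2 scale. The sizes of the first 3 of these rises depend on replicate 1 at 0 h, where Tnc stood at 11.45 CPM, Fbln2 at 9.97 and Spp1 at 4.17. Without that library the Tnc log2 fold change was 11.64, the Fbln2 log2 fold change 10.56 and the Spp1 log2 fold change 11.41. Collagen genes Col1a1 and Col3a1 rose by 7.21 and 7.47, and the collagen cross-linking enzyme Lox by 7.14. Sparc, already at 3524 CPM at 0 h, was not called at -0.01, and vitronectin (Vtn) fell by 1.87 (SE 0.35), with a Vtn log2 fold change of -2.46 without replicate 3 at 5 days. Replicate 3 at 5 days was the highest of its group for 28 of the 29 members that rose, and 5 members rather than 3 were lower without it. Camera called the list higher (adjusted p = 3.71e-16), with adjusted p = 0.237 with an estimated correlation.

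Contractile and mesenchymal genes rose in the same libraries. Of 33 tested, 24 rose and 1 fell, with a median log2 fold change of 1.52, and the counts were 24 and 1 when adjusted over the list alone. Smooth muscle actin (Acta2), a marker of myofibroblasts, rose from 215.7 ± 11.3 to 786.2 ± 255 CPM (n = 3), a log2 fold change of 1.87 (SE 0.19). Tagln rose by 7.74, with a Tagln log2 fold change of 8.38 without replicate 1 at 0 h, and Flna rose by 2.18. Vim and Cdh2, often used as mesenchymal markers, were not called, and Vim stood at 4674 CPM at 0 h and 4670 at 5 days. Anxa1 was the member that fell, by 1.01 (SE 0.11). Replicate 3 at 5 days was the highest of its group for 23 of the 24 members that rose. Camera called the list higher (adjusted p = 1.1e-12), with adjusted p = 0.169 with an estimated correlation.

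**Figure D2:**
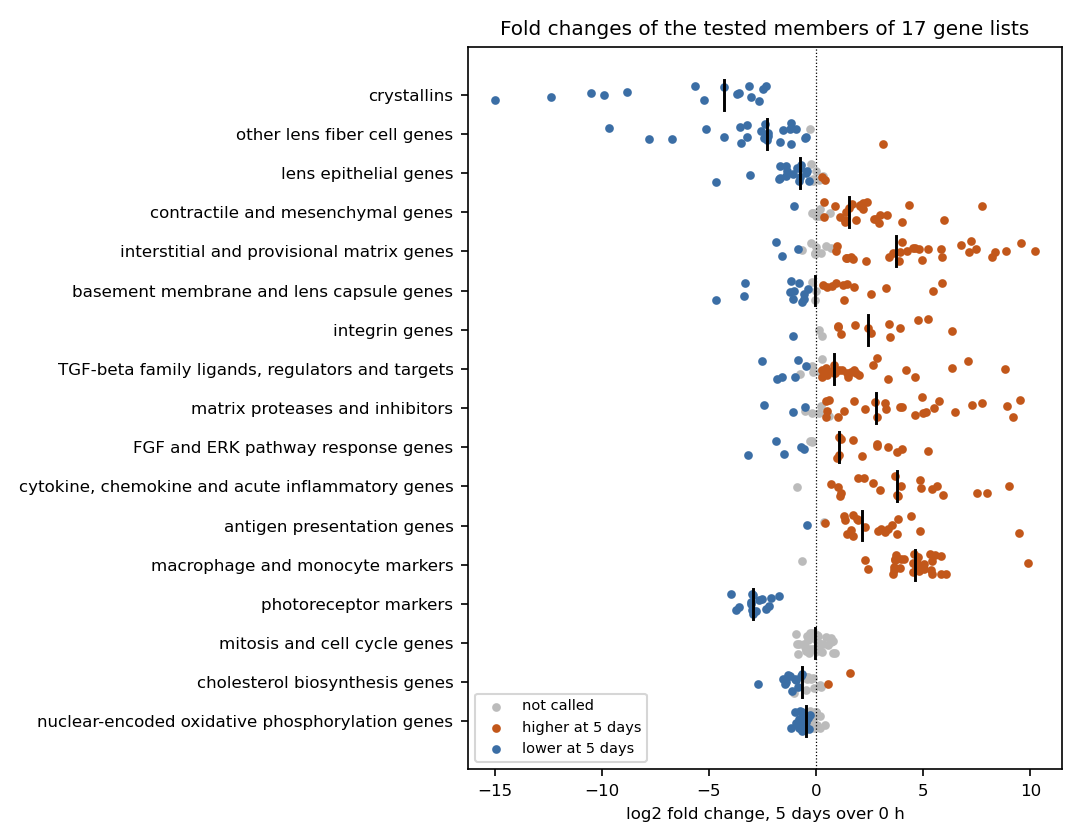
Log2 fold changes of 5 days over 0 h for the tested members of 17 fixed gene lists, with members called higher in orange, called lower in blue and not called in grey, and a black bar at each list's median. The medians run from -4.27 for crystallins to 4.60 for macrophage and monocyte markers, all 34 mitosis and cell cycle genes are grey, and fitted values of genes with no counts in a group, such as Crygb, are not bounds on the fold.

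Basement membrane and capsule genes went both ways, with 12 of 27 tested genes higher and 12 lower, also when adjusted over the list alone. The median log2 fold change was -0.06 with TMM and 0.07 with total library size. Type IV collagen genes differed: Col4a1 fell from 14970 ± 193 to 7276 ± 300 CPM (n = 3) and Col4a2 by 1.22 on the log2 scale, Col4a3 was not called at -0.16, and Col4a6 rose by 0.93. Npnt, Lama3 and Frem2 fell by 4.66, 3.36 and 3.30. Lama4 rose by 5.90 (SE 0.51), with a Lama4 log2 fold change of 6.63 without replicate 1 at 0 h, and Agrn rose by 2.58. Camera did not call the list (adjusted p = 0.319).

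Integrins, the cell receptors for matrix, rose as a group, with 12 of 15 tested higher and 1 lower, also when adjusted over the list alone, and a median of 2.42. Itga7 rose from 4.47 ± 0.471 to 365 ± 43.0 CPM (n = 3), Itgb1 rose by 2.42 and Itga5, the fibronectin receptor subunit, by 3.47. Itga6, a laminin receptor subunit, fell by 1.07 (SE 0.20). Matrix proteases and their inhibitors rose for 26 of 34 tested genes and fell for 3, with 28 higher and 3 lower when adjusted over the list alone. Mmp9 was 846.5-fold higher (95% counting interval 289.3 to 4108), and Mmp14, Timp1 and Plau rose by 4.60, 5.15 and 7.29. Some protease members, such as Mmp12, Mmp13 and Adamts14, had only 1, 2 and 1 counts over the 0 h libraries. Such members passed the filter through the libraries at 5 days and could hardly come out lower, which tilts the count and the camera call upward. Adamts5 fell by 2.44 (SE 0.11). Camera called integrins higher (adjusted p = 3.51e-09, and adjusted p = 0.169 with an estimated correlation). It also called the protease list higher (adjusted p = 4.95e-15, and adjusted p = 0.169 with an estimated correlation).

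Signalling genes of the TGF-beta family rose for 24 of 35 tested and fell for 6, with 25 and 7 when adjusted over the list alone and a median of 0.85. The 3 TGF-beta genes rose: Tgfb2 from 518.5 ± 14.1 to 1437 ± 148 CPM (n = 3), Tgfb1 by 2.66 and Tgfb3 by 1.63. Among other ligands Bmp6 and Inhbb rose by 2.85 and 0.85, and Bmp2, Bmp4 and Inhba were not called, at -0.18, -0.16 and 0.17. The target gene Pmepa1 rose by 4.21 (SE 0.14), and the BMP antagonist Grem1 was 667.4-fold higher (95% counting interval 119.4 to 26400). Grem1 stood at 18.94, 7.79 and 48.72 CPM in the 3 libraries at 5 days, and without replicate 3 the Grem1 log2 fold change was 7.88 against 8.83 with all libraries. The BMP response genes Id1 and Id2 and the ligand Bmp7 fell by 1.61, 2.51 and 1.81. Camera called the list higher (adjusted p = 2.19e-07), with adjusted p = 0.256 with an estimated correlation.

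YAP/TAZ target genes rose for 13 of 23 tested and fell for 5, also when adjusted over the list alone. Igfbp3 was 2207-fold higher (95% counting interval 610.6 to 18230), Axl and Ccn1 rose by 6.17 and 2.60, and Amotl2 fell by 0.987 (SE 0.12). The 2 Igfbp3 counts at 0 h lay in replicate 1, and without that library its fold is only a bound. FGF and ERK response genes rose for 12 of 20 tested and fell for 5, also when adjusted over the list alone, and 3 rather than 5 were lower without replicate 2 at 0 h. The ERK feedback phosphatases Dusp5 and Dusp6 rose by 5.24 and 2.84 and Etv4 by 4.01, while Etv1 and Spry2 fell by 0.68 and 0.56. Etv5 was not called, at -0.29. Receptors and ligands went both ways. The receptor Fgfr1 and the ligand Fgf2 rose by 1.00 and 3.77, and the receptors Fgfr2 and Fgfr3 and the ligand Fgf1 fell by 1.85, 1.47 and 3.19. Camera called the YAP/TAZ list higher (adjusted p = 7.29e-06) and the FGF list higher (adjusted p = 0.00239), each with adjusted p = 0.169 with an estimated correlation.

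Wnt and Notch genes went both ways, with 15 of 35 tested higher and 11 lower, also when adjusted over the list alone, and a median of -0.04 that was 0.09 with total library size. Heyl, Lef1 and Jag1 rose by 5.92, 4.37 and 2.90, and Wnt7a and Axin2 fell by 1.63 and 0.77. Camera did not call this list (adjusted p = 0.0652), but did without replicate 2 at 0 h, without replicate 2 at 5 days and with no low-count filter.

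Cytokine and acute inflammatory genes rose for 20 of the 21 tested of 44 listed, with a median of 3.80, and 20 were higher and 1 lower when adjusted over the list alone. Il6 was at least 67.5-fold higher, with no counts at 0 h against 7.98 ± 1.27 CPM at 5 days (n = 3). Members without counts at 0 h, Il6 among them, passed the filter through the libraries at 5 days and could only come out higher. Lif, Socs3 and Ccl2 rose by 4.84, 3.70 and 2.67. Il33 was not called, at -0.88, but was called lower without replicate 1 at 0 h, without replicate 3 at 5 days and with no filter. Antigen presentation genes rose for 20 of 22 tested and fell for 1, with 21 and 1 when adjusted over the list alone. B2m rose by 3.02, Cd74 and H2-Ab1 rose by 3.84 and 4.41, and the class II regulator Ciita was at least 88.5-fold higher. Interferon-stimulated genes rose for 19 of 30 tested and fell for 1, also when adjusted over the list alone, among them Gbp2 by 3.33 and Irf1 by 1.72. The filter limits these 2 lists too: Ciita had 0 counts at 0 h, and the interferon genes Gbp4 and Gbp5 had 2 each. Such members could hardly come out lower. Complement genes rose for 7 of 12 tested and fell for 3, with 8 and 3 when adjusted over the list alone. C3 rose by 2.95, and Clu, an abundant lens chaperone, fell from 5256 ± 204 to 2116 ± 295 CPM (n = 3). Reads of the H2 genes and of C4b are shared with close copies and are uncertain. Camera called the cytokine list higher (adjusted p = 3.73e-13, and adjusted p = 0.169 with an estimated correlation) and the antigen presentation list higher (adjusted p = 4.52e-10, and adjusted p = 0.169 with an estimated correlation). It called the interferon list higher (adjusted p = 0.000112, and adjusted p = 0.223 with an estimated correlation) and did not call complement (adjusted p = 0.207).

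Markers of other cell types moved with the same comparison. Macrophage and monocyte markers rose for 31 of 32 tested, also when adjusted over the list alone, with a median of 4.60. Of these 32, 16 reached a mean of 1 CPM at 0 h and 32 did at 5 days. Those below it at 0 h passed the filter through the libraries at 5 days and could hardly come out lower. The count and the camera call of this list are thus tilted upward. Lyz2 rose from 5.56 ± 3.98 to 241.8 ± 46.8 CPM (n = 3), with a Lyz2 log2 fold change of 5.43 that was 6.17 without replicate 3 at 0 h, C1qa by 5.06 and Csf1r by 3.70, and the monocyte receptor Ccr2 was at least 119.8-fold higher. Of 16 neutrophil markers 6 were tested and 6 rose, also when adjusted over the list alone, with a median of 6.55 that was 4.59 with genes of no counts at their bound, and 2 rose with the stricter low-count filter. None of the 6 reached 1 CPM at 0 h, so they passed the filter through the libraries at 5 days and could only come out higher. Of the 10 not tested, Ly6g, Camp, Elane, Mpo, Stfa2 and Stfa2l1 had no counts at either time, and S100a8, Retnlg, Ltf and Ngp had 0, 0, 1 and 0 counts at 0 h and 29, 7, 8 and 2 at 5 days. Csf3r rose from 0.199 ± 0.175 to 15.2 ± 2.78 CPM (n = 3), with a Csf3r log2 fold change of 6.14 with all libraries and 6.73 without replicate 2 at 0 h. No lymphocyte marker of 19 passed the low-count filter, and 2 were called higher with no filter and with DESeq2. Photoreceptor markers fell for 16 of 16 tested, also when adjusted over the list alone, with a median of -2.94. Replicate 3 at 5 days was the highest of its group for 13 of these 16 and for 6 of the 31 macrophage markers. The rod transducin gene Gnat1 fell from 123.9 ± 29.9 to 15.3 ± 7.27 CPM (n = 3). Vascular genes rose for 7 of 11 tested and fell for 2, with 8 and 2 when adjusted over the list alone, among them Flt1 from 24.0 ± 2.32 to 245.5 ± 11.9 CPM (n = 3), and 1 rather than 2 fell without replicate 1 at 0 h. The filter limits this list too, with 7 of the 11 at a mean of 1 CPM or more at 0 h and 11 at 5 days. Camera called macrophage markers higher (adjusted p = 1.42e-27) and vascular genes higher (adjusted p = 0.0137), each with adjusted p = 0.169 with an estimated correlation. It called photoreceptor markers lower (adjusted p = 8.81e-09, and adjusted p = 0.251 with an estimated correlation).

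Among pigment cell markers 2 of 8 tested fell, also when adjusted over the list alone. Those that fell were Oca2, by 5.94, and Trpm1, by 2.31, with an Oca2 log2 fold change of -6.59 without replicate 1 at 5 days. In addition, 1 member rose without replicate 3 at 0 h. Of the 8 tested members 2 are also in another list, so this list is not independent of the others. The pigment enzymes Tyr and Dct were not called, at 1.10 and 0.08. The list's median was 0.04 while camera called it lower (adjusted p = 0.00539, and adjusted p = 0.237 with an estimated correlation), so the median and the test differ in sign. Of 11 ciliary epithelium and zonule genes 2 rose and 3 fell, also when adjusted over the list alone. Fbn1 rose by 1.39 and Wfdc1 fell by 2.76, and 1 rather than 2 rose without replicate 1 or 2 at 0 h and with limma-voom. Camera did not call that list (adjusted p = 0.264). Of 4 corneal genes tested from 13 listed, Ecm1 and Lum rose, by 7.88 and 4.80, and Aldh3a1 and Krt15 fell, by 0.92 and 1.92, also when adjusted over the list alone, and 6 rose with no low-count filter. The surface keratins Krt14 and Krt5 were not tested, and nearly all their counts lay in replicate 3 at 5 days: 418 of 422 and 182 of 185 at that time, against 1 and 2 at 0 h. Camera called the corneal list higher (adjusted p = 0.0327, and adjusted p = 0.201 with an estimated correlation), and the call was lost without any library of 0 h or without replicate 1 at 5 days. No red blood cell gene passed the filter, and their share of counts was 0.000107 ± 5.19e-06% at 0 h and 0.000169 ± 0.000234% at 5 days (n = 3, exact two-sided permutation p = 1).

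**Figure D3:**
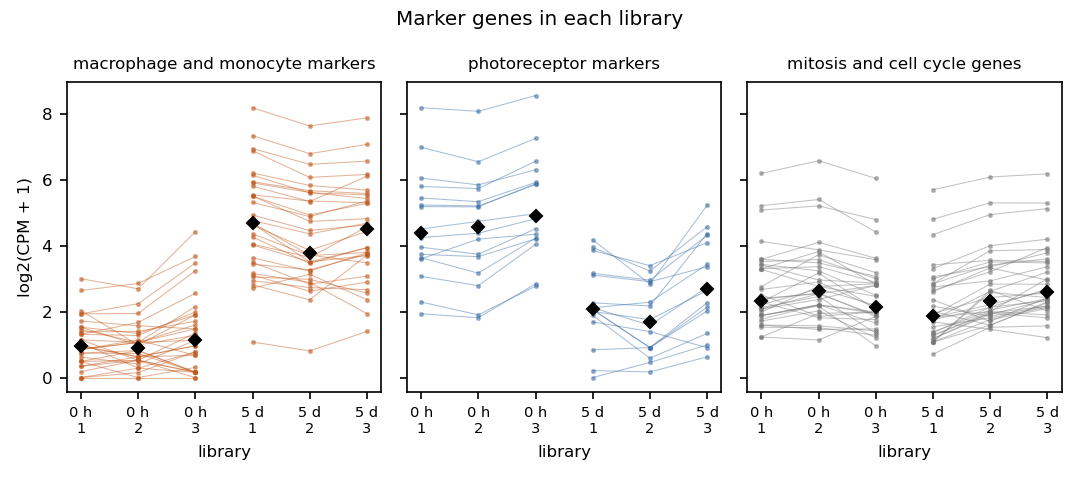
Markers of macrophages and monocytes, photoreceptors and dividing cells in each of the 6 libraries, as log2 of CPM plus 1, where each thin line is a gene within a group and each diamond the median of the list. The macrophage list is higher in the 3 libraries at 5 days, the photoreceptor list is lower, and the cell cycle list lies at similar levels at both times.

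None of 34 mitosis and cell cycle genes passed edgeR's quasi-likelihood test over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05 (lower), and DESeq2 and limma-voom each called 0. Mki67 stood at 77.5 ± 15.5 CPM at 0 h and 63.4 ± 10.9 at 5 days (n = 3), with a log2 fold change of -0.29 (SE 0.16). Without replicate 3 at 5 days 4 members were lower, Mki67 among them with a Mki67 log2 fold change of -0.40, and without replicate 1 at 5 days 2 members were higher. Of 34 DNA replication genes 2 rose and 2 fell, with 1 and 2 when adjusted over the list alone. Tyms and Pola2 rose, by 1.55 and 0.68, and Prim1 and Pola1 fell, by 1.56 and 0.74. The number that fell was 4 without replicate 3 at 5 days. The number that rose was 1 without replicate 1 or 3 at 0 h, without replicate 1 or 2 at 5 days, with no low-count filter and with DESeq2. Camera called neither list (adjusted p = 0.525 and 0.683).

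Stress response genes rose more often than they fell. Immediate early genes rose for 18 of 27 tested and fell for 5, with 18 and 6 when adjusted over the list alone. Egr3 was 105.6-fold higher (95% counting interval 35.8 to 514.7), Junb and Fos rose by 3.53 and 1.83, and the heat shock protein gene Hspb1 fell by 2.19 (SE 0.42), with a Hspb1 log2 fold change of -2.86 without replicate 3 at 5 days. The 3 Egr3 counts at 0 h lay in replicate 1, and without that library its fold is only a bound. Unfolded protein response genes rose for 22 of 26 tested and fell for 1, also when adjusted over the list alone, with a median of 0.84. Calr and the chaperone Hspa5 rose by 1.45 and 0.89, Ddit3 was not called at 0.03, and Herpud1 fell by 0.97. Camera called the immediate early list higher (adjusted p = 0.00275, and adjusted p = 0.539 with an estimated correlation) and the unfolded protein list higher (adjusted p = 0.00023, and adjusted p = 0.307 with an estimated correlation).

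Metabolic and antioxidant genes fell more often than they rose, except in glycolysis. Cholesterol synthesis genes fell for 12 of 24 tested and rose for 2, also when adjusted over the list alone, with log2 fold changes of -2.72 for Insig1 and -1.41 for Fdft1, while Ebp rose by 1.58. The count of 2 that rose was 4 with total library size, and 1 without replicate 1 or 3 at 0 h or replicate 1 or 3 at 5 days. Nuclear-encoded oxidative phosphorylation genes fell for 22 of 38 tested, and 23 when adjusted over the list alone, with a median of -0.45. Ndufa5 and Sdhb fell by 1.18 and 0.90. Mitochondrially encoded genes went from 5.62 ± 0.243% to 9.56 ± 1.65% of gene counts (n = 3, exact two-sided permutation p = 0.1, the smallest possible), mostly ribosomal RNA of the mitochondrion. Oxidative defence genes fell for 14 of 31 tested and rose for 8, with 15 and 9 when adjusted over the list alone, and a median of -0.08 that was 0.04 with total library size. The glutathione synthesis enzymes Gclc and Gss fell by 1.26 and 2.28, the metallothioneins Mt1 and Mt2 rose by 3.27 and 3.45, and Gstm1 and Gstm2, which share sequence, fell by 1.91 and 2.90. Glycolysis genes rose for 7 of 22 tested and fell for 3, also when adjusted over the list alone, and 6 fell without replicate 3 at 5 days. The lactate transporter Slc16a3 rose by 1.82 and Aldoc fell by 2.68. Camera called the cholesterol list lower (adjusted p = 0.0012, and adjusted p = 0.42 with an estimated correlation) and the oxidative phosphorylation list lower (adjusted p = 0.0012, and adjusted p = 0.399 with an estimated correlation). It did not call oxidative defence (adjusted p = 0.0677), though it did without replicate 1 at 0 h, without replicate 1 or 3 at 5 days and with no filter, or glycolysis (adjusted p = 0.94).

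The genes with the largest changes among abundant transcripts included several outside these groups. Serpina3n, a secreted protease inhibitor, rose from 13.6 ± 2.12 to 6944 ± 2413 CPM (n = 3), and Tnfrsf11b, the decoy receptor osteoprotegerin, rose by 9.12 (SE 0.39). Arginase 1 (Arg1) rose by 9.67 (SE 0.73), and the muscle cadherin Cdh15 was 1055-fold higher (95% counting interval 360.6 to 5118). The 3 Cdh15 counts at 0 h lay in replicate 3, and without that library its fold is only a bound. Adamts16 rose by 8.86 (SE 0.38). Without replicate 1 at 0 h the Tnfrsf11b log2 fold change was 10.39 and the Arg1 log2 fold change 10.94, both resting on few counts at 0 h, and Adamts16 had no counts left at 0 h. Emilin3, Scube3 and Plk5 fell, with log2 fold changes of -6.00, -4.74 and -4.31, as did Lctl, a lens gene of the fiber list, at -4.29. Without replicate 2 at 5 days the Emilin3 log2 fold change was -7.81 and the Lctl log2 fold change -5.09.

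Of the 31 lists that could be tested, camera with its preset correlation called 16 higher, the neutrophil markers among them, and 7 lower, and 0 were called with an estimated correlation. The preset test also called 11 to 21 lists when the 6 libraries were split in the 9 other ways, so a camera call here does not by itself separate the real grouping from the others. In each of those 9 splits 2 libraries of one time were put with 1 of the other. Part of the difference between the times stayed between their groups, so 11 to 21 is not a rate of false calls. No gene was called in any of the 9 splits, but the spread within their groups held the difference between the times.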

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

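The number of genes called was 6151 to 7535 over all alternatives against 6984, the genes changed by at least 2-fold were 3412 to 4427 against 3722, and no gene called in both took the opposite sign. DESeq2 called 6710 genes, limma-voom 7105, total library size 7051 and no filter 7535 (28203 genes tested). Without markers of other cell types, a count added after seeing the data, 6890 genes were called and 3633 were genes changed by at least 2-fold, with 3634 genes higher at 5 days and 3256 genes lower at 5 days. That count only leaves out the listed marker genes. RNA of other cells in the remaining genes stays in, so the count does not test whether calls depend on other cells. Of the named genes' values, 1465 kept their side of the threshold, 31 lost the call and 1 gained it. By camera 16 lists were higher and 7 lower, and with an estimated correlation 0 and 0; the calls were also lost for lists whose estimated correlation was near or below 0 (FGF and ERK genes -0.036, vascular genes 0.008), and the cause was not tested. The directional test of fry called 18 lists higher and 8 lower. The share of counts, red blood cell genes (percentage points, 5 days minus 0 h), differed by 6.218e-05 and lay between -7.317e-05 (without 5 day replicate 2) and 0.00013 with 1 library left out, the cause of which was not tested. Replicate blocks gave 6738 genes by title number and 6720 by library name number, where numbers 1 and 3 match and the third block joins the 2 libraries left over, numbered 2 and 7. Correlations of paired deviations over 9540 genes were 0.027, -0.065 and 0.064 by title and 0.027 and 0.013 by library name (0.001 for the 2 left over), none above 0.1, and not every library correlated best with its own number, so pairs were not used. Genes with few counts are limited by depth: 21 of 44 cytokine genes, 6 of 16 neutrophil markers and none of 19 lymphocyte markers had enough counts to test.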

Other observations

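All tests of patterns in this part were chosen after the results were seen, while the counts of other splits were planned before.

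The gene groups in this and the next paragraph were composed after their values were seen and were not tested as groups. Of 16 listed genes of the muscle membrane and satellite cells 7 were tested, of which 4 rose and 2 fell, with the membrane repair protein Dysf higher by 6.63, Itga7 by 6.35 and the muscle intermediate filament Des by 3.19, and with dystrophin (Dmd) lower by 1.62. The satellite cell and myogenic regulators Pax7, Pax3, Myf5, Myod1 and Myog had no counts at either time.

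Genes of plasminogen activation and protease inhibition rose for 11 of 12 tested. Plat rose from 15.8 to 253 CPM, the urokinase receptor Plaur was 679.1-fold higher (95% counting interval 121.5 to 26870), and Serpinf1 and A2m rose by 6.94 and 2.87. Of 16 listed genes known from wound keratinocytes 8 were tested, of which 4 rose and 2 fell: Itgb4 and Sfn rose by 4.75 and 2.20, and Krt19 and Lama3 fell by 1.28 and 3.36. Among those not tested, replicate 3 held 236 of the 255 counts of Col17a1, 87 of the 88 of Krt6a and 44 of the 53 of Krt17 at 5 days, against 7, 5 and 3 at 0 h.

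Photoreceptor markers were lower at 5 days, with median levels of 0.87, 0.827 and 1.291 of the 0 h mean in the 3 libraries at 0 h and 0.118, 0.075 and 0.198 at 5 days. Library scaling did not account for this, since the median log2 fold change nearest to 0 under other scalings was -2.81. One hypothesis is retinal RNA in the samples, more of it at 0 h: deviations from the group means of the 16 markers had a mean pairwise correlation of 0.646, where 95% of 1000 random lists matched on expression lay below 0.088. Of 31 other retinal genes tested 22 were lower, 1 (Tfap2b) was higher and 8 were not called, but that list was composed after its values were seen, so its count tests nothing. Lens cells regulating these genes together would give the same covariation, so the test does not decide between the 2, and a change of expression in the lens cells stays open.

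Crystallin and fiber genes were lower at 5 days under every scaling, with a crystallin median nearest to 0 of -4.14. A loss of one kind of fiber cell, alike for all fiber genes, was argued against by the difference of -4.51 between the median of all 7 tested γ-crystallins (-6.81, SD 3.64) and that of all 25 tested genes of the other fiber list (-2.30, SD 2.32), although the 2 sets overlap, with Crygs at -3.01. One hypothesis is that remnants of mature fiber cells were left in the 0 h capsules: Crygb to Crygf, Birc7, Dnase2b and Clic5, picked for being at or near 0 at 5 days, had a mean pairwise correlation of 0.693 at 0 h, where 95% of random lists lay below 0.279. That value rests on 3 libraries, with median levels of 1.585, 0.6 and 0.826 of the 0 h mean, and on genes that share sequence. Lens cells regulating these genes together would give the same covariation, so lower expression in the remaining epithelial cells stays open beside it.

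Macrophage markers were higher at 5 days under every scaling, with a median of 4.60 in the report and, nearest to 0 under the 3 other scalings, 4.61. One hypothesis is that leukocytes were part of the 5 day samples: deviations of the 32 markers had a mean pairwise correlation of 0.198, where 95% of random lists lay below 0.045. Lens cells switching these genes on together would give the same covariation, so the test does not decide between the 2. Replicate 3 at 5 days was the highest for 6 of the 31 markers that rose, against 28 of 29 matrix genes.

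Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real grouping, the real one itself, which is too few splits for a share under 0.05. The real grouping gave 6984 genes and 3722 of at least 2-fold, where the highest other split gave 0 and 0. It gave 23 lists, where the others gave 11 to 21. Every other split mixed both times within each group, so the spread within groups held the difference between the times. Part of that difference also stayed between the groups. Neither the 0 nor the 11 to 21 is therefore a level expected without a difference.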
